A study of Mus musculus with 21 samples.

How the data were processed

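The series holds 21 arrays of mouse intestinal organoid RNA, 1 array per sample, with the same reference RNA on every array. The sample was labelled with Cy3 and the Universal Mouse Reference RNA with Cy5, without dye swaps. Per the file headers, the slides were scanned and quantified with Agilent Feature Extraction 10.7.3.1, and probe coordinates are those of the mouse build mm9. The deposited scanner files give for each spot the mean and background intensity of both channels as scanned, with flags for spots well above background, non-uniform or saturated. The deposited files also give a log10 ratio, made by Feature Extraction per the file headers, of reference over sample after Agilent's own background subtraction and dye normalization. The deposited series matrix holds log2 ratios of sample over reference; the tool that made it is not given in the sources used here.

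Each array had 62976 spots, of which 3671 control spots were left out; averaging the spots of a probe (432 probes had several, at most 10) left 55681 probes. Over all arrays 157 spots were flagged as non-uniform and given a missing value, and no spot was saturated. The share of spots well above background ranged from 42.6% to 51.9% in the sample channel and from 50.2% to 60.1% in the reference channel. In R 4.3.3 with limma 3.58.1 and the package data.table (version 1.17.8), the intensities were background-corrected with normexp and an offset of 50 and normalised within each array by loess to log2 sample over reference. Probes well above background in Cy3 on at least 3 arrays were kept (29628), and each gene symbol was represented by its brightest probe. This left 21487 genes, 5695 of them with more than 1 probe; 13838 matched a RefSeq gene by accession, 13783 had an approved-style symbol and 2728 were long non-coding regions. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

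Groups were taken from the labels. Letters A to C and D to G of the titles form sets that were scanned on 2 days with 2 scanners. A single limma model was fitted to all arrays with a term for each of the 5 groups and a term for the set, so that each comparison is one against vehicle arrays with the same letters. The scan day is identical to the set and cannot be told apart from it. Vehicle, compound 2 and compound 9 of set A to C share slides, and set D to G lies on 3 other slides, of the 5 in all. Moderated tests were two-sided and adjusted over genes by Benjamini-Hochberg with a threshold of 0.05. The p-values measure the spread between these samples; the labels do not say whether they are separate cultures or animals. The median SD between arrays of a group was 0.110 for compound 2, 0.139 for compound 6, 0.118 for compound 9, 0.117 for withdrawal, 0.115 for vehicles A to C and 0.148 for vehicles D to G. The leading principal components held 63.9%, 12.4% and 7.22% of the variance. On the first, arrays A to C lay at -59.6 to -38.7 and arrays D to G at 15.8 to 54.8, so it parts the sets and their scans.

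Whether the letters pair the samples was checked on deviations from the group means. The 21 pairs of arrays with the same letter in different groups correlated at 0.208 to 0.749 (median 0.529), pairs with other letters at a median of -0.179, and for 18 of 21 arrays the best partner had the same letter. The letter was therefore also fitted as a block in place of the set, and its value is given beside counts of passing genes and beside single genes and lists. Counts of list members and of 2-fold changes are from the fit with the set term alone. They could be higher with the block, which gave 8389, 3707 and 8853 passing genes for withdrawal and compounds 2 and 6, in place of 4449, 1130 and 5323. No array was identical to another (highest correlation 0.996).

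The 20 gene lists were fixed from general knowledge before the data were examined, as were the comparisons, the filters, the rule for named genes and all alternatives not marked otherwise. The lists cover Wnt/beta-catenin targets, intestinal stem cells, fetal or regenerative epithelium, Paneth, goblet, enteroendocrine, enterocyte and tuft cells. They also cover the cell cycle, Myc and ribosome biogenesis, interferon-stimulated genes, the Mediator kinase module, cholesterol and fatty acid synthesis, p53 targets, the unfolded protein response, immediate early genes, and hypoxia and glycolysis. The last 3 hold markers of fibroblasts, leukocytes and endothelium. Each list was tested with limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated for each list. With the estimated correlation only the goblet list between compounds 9 and 2 passed, of 20 lists in 10 comparisons, and with the letter as a block as well only the enteroendocrine list of compound 6 against vehicle, compound 2 and compound 9. The median, the mean and the test differed in sign for 3 lists after withdrawal (Paneth cells, fibroblasts and endothelium), 9 with compound 9 and 0 with compounds 2 and 6, and for 0 to 5 in each of the other comparisons, and none of these lists passed.

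For a comparison with vehicle, the named genes are the 10 largest rises and falls past the threshold with an approved-style symbol and signal well above background on every array of 1 of the 2 groups. To these come a fixed panel of 17 genes and up to 4 members of each list that passed; between other groups, the 5 largest differences each way and the panel. The text prints part of them. Where a group was not well above background on any array, a bound on the fold ("at least") from the Cy3 levels against the background level stands beside the change. It is left out across the sets, which the Cy3 levels do not allow for, and for Pla2g5, where it exceeded the fold of the ratios. Of the named genes that passed and have several probes, another probe had the opposite sign for 1 of 14 after withdrawal, 0 of 10 with compound 2 and 3 of 20 with compound 6. Another probe showed under 50% of the change, a count made after the data were seen, for 7, 6 and 11 of these genes.

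The alternatives were Agilent's log ratios, loess followed by scaling of average intensities between arrays, the Cy3 channel alone, the series matrix, no filter, a filter on every array, the mean of a gene's probes, no set term, the letter, slide or scan day as a block, the arrays of the compared groups alone, and trend, robust and array weight options. Each array was also left out in turn. Leaving out every letter F array, and the slide block for the lists, were chosen after seeing the data. For slides with 1 array on a side only list medians are given, since a test there would rest on the spread of other arrays.

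The series matrix was checked against log2 ratios of the background-subtracted signals in the scanner files, which carry no dye normalization. Across spots, controls included, they correlated at 0.991 to 0.998 on each array with slopes of 0.980 to 0.997. For 100.0% of spots a value was missing in both or in neither. The medians of the matrix columns were 0.0710, 0.106 and 0.0755 for compound 2 A to C, 0.0821, 0.0997 and 0.0778 for compound 9 A to C, and 0.0325, 0.0344, 0.0669 and 0.0360 for compound 6 D to G. They were 0.0411, 0.0420, 0.0689 and 0.0527 for withdrawal D to G, and 0.0756, 0.101, 0.0789, 0.00385, 0.00604, 0.0439 and 0.0249 for vehicles A to G.

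The fit was tested on simulated data with 200 changed genes among the 21425 without missing values. In the design of the withdrawal comparison it recovered 71.6%, 95.5% and 98.5% of changes of 0.5, 1 and 2 on the log2 scale, with 8 false calls of 185. In that of compound 2 it recovered 47.8%, 97.0% and 100.0%, with 5 false calls of 168. A list lowered by 0.5 was found in both, and 0 of 19 other lists were. The simulated noise was independent between genes and between arrays, so it held neither correlation within lists nor pairing by letter. False calls of lists or genes that arise from these in the real data are therefore not covered.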

Results

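Gene expression was measured on 21 dual-channel Agilent arrays in mouse small-intestinal organoids, epithelial cultures grown in gel from isolated crypts. The cells carried a transgene for a truncated human beta-catenin, the transcriptional effector of Wnt signalling, which is made while doxycycline is in the medium. With doxycycline present, 7 arrays held vehicle-treated cultures (letters A to G), 3 compound 2 (A to C), 3 compound 9 (A to C) and 4 compound 6 (D to G), each compound at 2 µM for 24 h. On 4 further arrays (D to G) doxycycline had been withdrawn for 24 h. Per the labels, the compounds belong to a 3,4,5-trisubstituted pyridine series and inhibit CDK8 and CDK19, the kinases of the Mediator complex. In the sample channel 42.6% (compound 6 F) to 51.9% (compound 9 A) of spots stood well above background, and 21487 genes were tested; the number of arrays limits the precision. Values below are log2 changes ± SE against the vehicle arrays with the same letters, positive where higher than vehicle.

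Withdrawal of doxycycline ends the induction of the mutant beta-catenin (4 arrays against 4). The series holds no cells without the transgene, so an effect of doxycycline itself cannot be told apart. Ascl2, a transcription factor of intestinal stem cells and a Wnt target, fell from 4.15 ± 0.57 to 0.96 ± 0.13 (log2 sample over reference, mean ± SD, n = 4 each), a change of -3.19 ± 0.32 (adjusted p = 1.21e-05, lower in 4 of 4 letters). Its probe lies on chromosome 7 from 150152734 to 150152793 (mm9). The stem cell receptor Lgr5 fell by 2.51 ± 0.46 (adjusted p = 0.00127) and the Wnt feedback gene Rnf43 by 2.29 ± 0.23 (adjusted p = 1.21e-05). Axin2, the classical Wnt feedback target (chromosome 11, 108812034 to 108812093), fell by 1.36 ± 0.22 (adjusted p = 5.49e-04, at least 2.37-fold; -0.47 on its other probe). The potassium channel subunit Kcne3 fell by 3.12 ± 0.47 (with the series matrix it lay at 1.97), the phospholipase Pla2g5 by 3.56 ± 0.36 (not well above background on any withdrawn array; -0.63 on its other probe), Myc by 2.08 ± 0.22 (adjusted p = 1.53e-05), Lef1 by 1.31 ± 0.12 and Tcf7 by 0.99 ± 0.09 (at least 1.85-fold; -0.07 on its other probe).

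The fixed gene lists were tested next, and none of the 6 that passed with the preset correlation passed with an estimated one. Of 28 measured Wnt/beta-catenin targets 15 fell, 2 rose and 11 did not pass (the same numbers adjusted over the list alone; median -0.50, camera adjusted p = 1.81e-07, 0.204 with an estimated correlation). Of 25 intestinal stem cell genes 19 fell and 6 did not pass (19 adjusted over the list alone; median -0.98, adjusted p = 2.92e-12, 0.124 with an estimated correlation). Of 24 genes of Myc and ribosome biogenesis 23 fell and 1 did not pass (23 adjusted over the list alone; median -1.07, adjusted p = 9.74e-16, 0.31 with an estimated correlation), among them Polr1b at -1.34 ± 0.20 and Nop2 at -1.15 ± 0.18. Of 26 cell cycle genes 20 fell and 6 did not pass (26 fell adjusted over the list alone; median -1.13, adjusted p = 5.47e-11, 0.529 with an estimated correlation), with Uhrf1 at -2.49 ± 0.51, Mcm4 at -1.79 ± 0.33 and Pcna at -0.98 ± 0.13. The median fall of the cell cycle list was -1.35, -1.34 and -1.83 in letters D, E and G and -0.17 in letter F. Beside this, vehicle F stood apart in the cell cycle list, at -3.72 against -1.82 to -1.61 in vehicles D, E and G, and in the Myc and ribosome list, at -1.94 against -0.88 to -0.72.

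Of 30 enterocyte genes 7 rose and 23 did not pass (9 adjusted over the list alone; median 0.17, adjusted p = 1.19e-05, 0.529 with an estimated correlation). They included the amino acid transporter Slc6a19 at 0.76 ± 0.19 (adjusted p = 0.01), lactase, Lct, at 0.63 ± 0.17 and sucrase-isomaltase, Sis, at 0.46 ± 0.11. The enteroendocrine list passed with 1 of 23 members higher and 22 not passing (0 adjusted over the list alone; median 0.14, adjusted p = 0.044, 0.529 with an estimated correlation). Gclc, which encodes the catalytic subunit for glutathione synthesis, rose by 1.23 ± 0.17 (adjusted p = 1.96e-04), and Pck1, the gluconeogenic enzyme, rose by 1.26 ± 0.28 (adjusted p = 0.00443). The remaining 14 lists did not pass, from interferon-stimulated genes (2 rose, 1 fell of 26; adjusted p = 0.0696) to Paneth cell genes (1 rose of 15; adjusted p = 0.964). With the letter as a block, tuft cell and interferon-stimulated genes passed as well (adjusted p = 0.0138 each), though not with an estimated correlation besides (0.425 and 0.525). Cdk8 (0.06 ± 0.08), Cdk19 (-0.14 ± 0.09) and mouse Ctnnb1 (0.05 ± 0.05) did not pass. The Ctnnb1 probe is of mouse sequence, and whether it also detects the human transgene was not tested.

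With limma, 4449 genes passed on withdrawal, 1568 higher and 2881 lower; 26 rose and 290 fell by at least 2-fold. With the letter as a block the count was 8389. The share of passing genes that were higher, 35.2%, was 47.2% with Agilent's log ratios, 46.6% with the Cy3 channel alone and 46.3% with the series matrix. Without 1 array the count was 7411 (vehicle F), 2422 (vehicle E), 2729 (vehicle D) or 2917 (vehicle G). It was 6850 without every letter F array, 2126 without the set term and 2086 with only the arrays of these groups. Within 1 slide holding 3 withdrawn arrays and 1 vehicle array the list medians were -0.95 for Wnt targets, -1.11 for stem cell and -1.66 for cell cycle genes. On another, with 1 withdrawn array and 2 vehicle arrays, they were -0.38, -0.76 and -0.93.

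**Figure D1:**
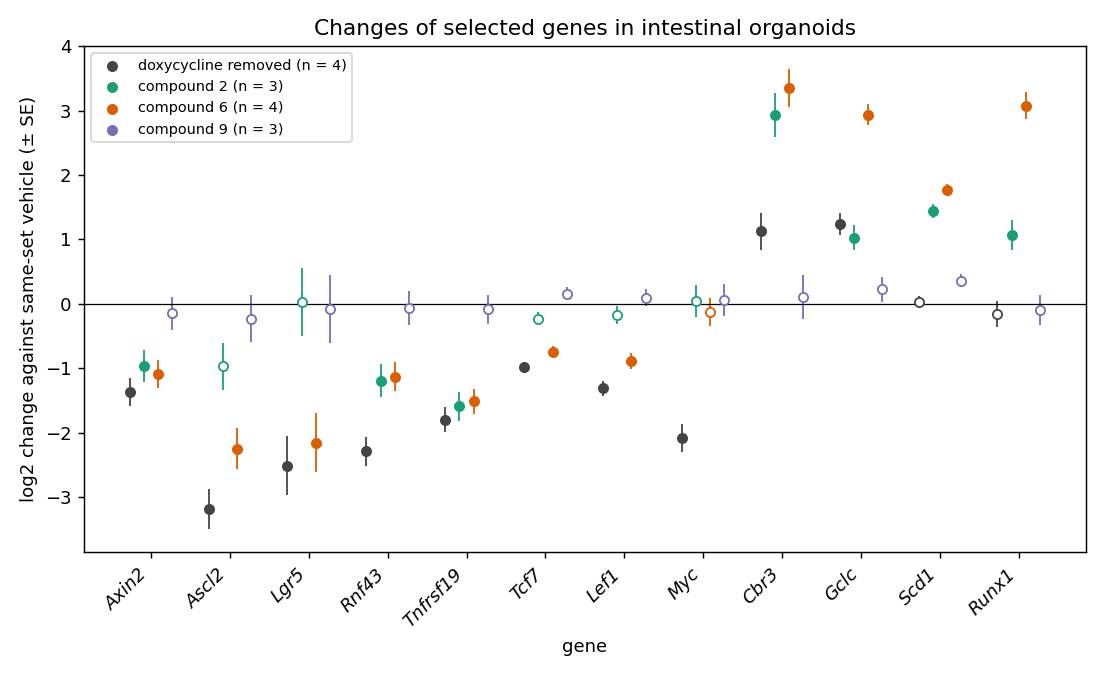
Log2 change ± SE (y axis) of 12 genes (x axis) against the vehicle arrays with the same letters, after doxycycline withdrawal and with compounds 2, 6 and 9 (n = 4, 3, 4 and 3); filled points have an adjusted p under 0.05. Myc lies at -2.08 after withdrawal and at -0.12 with compound 6, while Cbr3 lies at 2.93 with compound 2 and 3.35 with compound 6.

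Compound 2 was compared with vehicle to show what a CDK8/19 inhibitor does while mutant beta-catenin stays induced (3 arrays against 3). Cbr3, a carbonyl reductase, rose from -2.34 ± 0.55 to 0.60 ± 0.47 (mean ± SD, n = 3 each), by 2.93 ± 0.34 (adjusted p = 4.82e-05, higher in 3 of 3 letters; chromosome 16, 93691120 to 93691179). The glutathione transferases Gstm1 and Gstm4 rose by 2.11 ± 0.15 and 1.84 ± 0.13 (adjusted p = 1.28e-07 each; the other Gstm4 probe lay at 0.50). The fatty acid desaturase Scd1 rose by 1.44 ± 0.10 (adjusted p = 1.28e-07; chromosome 19, 44469387 to 44469446), the elongase Elovl6 by 0.67 ± 0.08 and the acute-phase gene Saa2 by 2.33 ± 0.20 (at least 3.65-fold). The Wnt target Tnfrsf19 fell by 1.59 ± 0.23 (adjusted p = 4.37e-04; -0.43 on its other probe), the sorting receptor Sort1 by 1.24 ± 0.12 (adjusted p = 9.63e-06; -0.69 and -0.0375 on its other probes) and the cytochrome Cyp2c70 by 1.32 ± 0.17. Rnf43 fell by 1.19 ± 0.26 (adjusted p = 0.0116) and Axin2 by 0.97 ± 0.25 (adjusted p = 0.0289), while the other Axin2 probe lay at -0.0739.

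Both of these calls were lost when 1 of several arrays was left out, which also lowers power. The changes then ranged from -1.21 to -0.81 for Axin2 and from -1.46 to -0.98 for Rnf43. The adjusted p of Axin2 was 0.144 without compound 2 A, 0.11 without compound 2 C, 0.0774 without vehicle A and 0.116 without vehicle B. That of Rnf43 was 0.0547, 0.0721 and 0.0587 without compound 2 A, compound 2 C and vehicle B. Ascl2 lay at -0.97 ± 0.36 (adjusted p = 0.143, with the letter as a block 0.00885), Lgr5 at 0.03 (95% interval -1.08 to 1.13) and Myc at 0.04 (-0.49 to 0.57). Of 28 Wnt/beta-catenin targets 4 fell and 24 did not pass (4 adjusted over the list alone), and the list itself did not pass (median -0.02, adjusted p = 0.137). Of 25 stem cell genes 4 fell, 1 rose and 20 did not pass (5 fell and 1 rose adjusted over the list alone; adjusted p = 0.137). The median of that list started lower in vehicles A to C (0.49 ± 0.20) than in D to G (1.09 ± 0.59), and so did Myc. Without the set term, Lgr5 with compound 2 lay near its level after withdrawal. Both limit what the small changes of Lgr5 and Myc can show. Cdk8 (0.25 ± 0.09) and Cdk19 (-0.32 ± 0.10) did not pass; with the letter as a block their adjusted p was 0.0179 and 0.0129.

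The lists that passed with compound 2 were of goblet cells, lipid synthesis, enterocytes and interferon response. Of 18 goblet cell genes 1 rose and 17 did not pass (1 adjusted over the list alone; median 0.25, adjusted p = 1.64e-04, adjusted p = 0.066 with an estimated correlation). Of 26 genes of cholesterol and fatty acid synthesis 5 rose and 21 did not pass (7 adjusted over the list alone; median 0.14, adjusted p = 1.64e-04), with the sterol carrier Stard4 at 0.48 ± 0.10. The enterocyte list (3 rose, 1 fell, 26 did not pass of 30; median 0.18) passed at 0.00564 and the interferon-stimulated list (1 fell, 25 did not pass of 26; median -0.15) at 0.00919. With an estimated correlation the adjusted p was 0.426 for lipid synthesis and 0.65 for both of the latter. The other 16 lists did not pass, from Paneth cell genes (2 rose of 15; adjusted p = 0.137, with the letter as a block 0.0408, with an estimated correlation besides 0.446) to the Mediator kinase module (0 of 6; adjusted p = 0.553). Tuft cell genes (0 of 15; adjusted p = 0.137) passed with the letter as a block (0.00121), though not with an estimated correlation besides (0.446). Cell cycle genes had a median of 0.07 (2 rose, 24 did not pass of 26; adjusted p = 0.372), in vehicle arrays A to C that lay low at the start, at -3.82 ± 0.06.

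With limma, 1130 genes passed with compound 2, 706 higher and 424 lower, 89 and 23 of them by at least 2-fold. The count was 3707 with the letter as a block, 3636 without the set term, 2299 without every letter F array and 651 with only the arrays of these groups. It was 546 without compound 2 A, 599 without compound 2 C, 627 without vehicle A and 725 without vehicle C. The share higher, 62.5%, was 48.8% with Agilent's log ratios and 49.7% with the Cy3 channel alone. Within the slide that held letters A and B 21 genes passed; the slide of letter C, with 1 array a group, allowed no test. The Wnt list median was -0.05 on each of these slides.

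Compound 6 was compared with vehicle on letters D to G (4 arrays against 4), at the dose and time of compound 2. Gclc rose by 2.94 ± 0.17 (adjusted p = 3.7e-09) and Cbr3 by 3.35 ± 0.29 (adjusted p = 3.96e-07), each in 4 of 4 letters. The transcription factor Runx1 rose from -1.57 ± 0.27 to 1.51 ± 0.54 (mean ± SD, n = 4 each), by 3.08 ± 0.20 (adjusted p = 1.88e-08; chromosome 16, 92605785 to 92605844). The growth factor Fgf18 rose by 2.94 ± 0.21, the aldo-keto reductase Akr1b8 by 3.01 ± 0.29 and Scd1 by 1.77 ± 0.09 (adjusted p = 1.2e-09). Ascl2 fell by 2.25 ± 0.32 (adjusted p = 7.47e-05), Lgr5 by 2.16 ± 0.46 (adjusted p = 0.00211), Tnfrsf19 by 1.51 ± 0.20, Axin2 by 1.08 ± 0.22 (adjusted p = 0.00143), Lef1 by 0.89 ± 0.12 and Tcf7 by 0.75 ± 0.09 (at least 1.63-fold). The other probes of Tnfrsf19, Axin2 and Tcf7 lay at -0.17, -0.41 and -0.18. Myc lay at -0.12 ± 0.22 (95% interval -0.58 to 0.33). The probes of Mup4, Mup3 and Mup20, genes for urinary proteins, fell by 2.78 ± 0.58, 2.51 ± 0.62 and 2.44 ± 0.63; these paralogs are so alike that a probe cannot be assigned to 1 of them with certainty.

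In the stem and Wnt lists most passing members fell; none of the 13 lists that passed with the preset correlation passed with an estimated one. Of 25 stem cell genes 16 fell and 9 did not pass (18 fell and 1 rose adjusted over the list alone; median -0.65, adjusted p = 1.67e-06, 0.188 with an estimated correlation). Of 28 Wnt/beta-catenin targets 13 fell, 2 rose and 13 did not pass (13 fell and 4 rose adjusted over the list alone; median -0.28, adjusted p = 0.015, 0.442 with an estimated correlation); Notum, a secreted Wnt inhibitor, rose by 0.39 ± 0.07. Of 26 cell cycle genes 8 fell, 1 rose and 17 did not pass (12 fell and 1 rose adjusted over the list alone; median -0.77, adjusted p = 3.06e-04, 0.513 with an estimated correlation). Mcm4 fell by 1.44 ± 0.33 and Pcna rose by 0.57 ± 0.13, while Mki67 lay at -1.17 ± 0.60 (adjusted p = 0.169, with the letter as a block 0.00155). Vehicle F, at -3.72 in that list, stood apart here too. Of 24 genes of Myc and ribosome biogenesis 3 fell and 21 did not pass (1 adjusted over the list alone; median -0.24, adjusted p = 0.0389, 0.708 with an estimated correlation). Cdk19 fell by 0.32 ± 0.09 (adjusted p = 0.0109); Cdk8 lay at 0.17 ± 0.08 (adjusted p = 0.108, with the letter as a block 0.0244).

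Of 23 enteroendocrine genes 10 rose and 13 did not pass (11 adjusted over the list alone; median 0.44, adjusted p = 1.1e-06, 0.114 with an estimated correlation), including the hormone Pyy at 0.80 ± 0.16 and the transcription factor Neurod1 at 0.65 ± 0.11 (-0.09 with Agilent's log ratios). Of 18 goblet cell genes 7 rose and 11 did not pass (median 0.36, adjusted p = 9.2e-05, 0.0642 with an estimated correlation), with the secretory regulators Atoh1 at 1.05 ± 0.21 and Spdef at 0.82 ± 0.15 and the Notch ligand Dll4 at 1.14 ± 0.12 (adjusted p = 3.58e-06). Enterocyte genes (7 rose, 2 fell, 21 did not pass of 30; median 0.16, adjusted p = 7.35e-04) and Paneth cell genes (4 rose, 11 did not pass of 15; median 0.12, adjusted p = 0.0147) passed as well. So did cholesterol and fatty acid synthesis (8 rose, 1 fell, 17 did not pass of 26; median 0.17, adjusted p = 0.00278), immediate early genes (6 rose, 11 did not pass of 17; median 0.21, adjusted p = 0.0147) and fetal epithelium genes (2 rose, 15 did not pass of 17; median 0.18, adjusted p = 0.0419).

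Markers of other cell types moved with these lists: 7 of 13 leukocyte genes rose (median 0.20, adjusted p = 3.06e-04), with Csf1r at 1.05 ± 0.15 (0.68 and 0.26 on its other probes). Itgam lay at 0.55 but at 0.0144 and -0.0338 on its other probes, and Laptm5 at 0.25 but at -0.0457 on its other probe, losing its call in 5 of 8 fits without 1 array. Of 11 fibroblast genes 5 rose (median 0.19, adjusted p = 0.0041), with Vim at 0.55 ± 0.11 from -7.29 in vehicle. With an estimated correlation the adjusted p was 0.114 for leukocytes, 0.369 for lipid synthesis and for fibroblasts, and 0.442 for the enterocyte, Paneth, immediate early and fetal lists. With the letter as a block the enteroendocrine list held even so (0.00674). The other 7 lists did not pass, from p53 targets (1 rose, 4 fell of 19; adjusted p = 0.0602) to endothelium (1 rose, 1 fell of 6; adjusted p = 0.976). With the letter as a block 3 of them passed: p53 targets (0.022), tuft cell genes (0.00369) and the unfolded protein response (0.00416). None of the 3 did with an estimated correlation besides (0.286, 0.262 and 0.23).

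With limma, 5323 genes passed with compound 6, 2439 higher and 2884 lower, 187 and 182 of them by at least 2-fold. The count was 8853 with the letter as a block and 3091 with only the arrays of these groups, and the Wnt list did not pass without the set term (adjusted p = 0.185). On the slides with 2 compound arrays and 1 vehicle array, 1 and 1, and 1 and 2, the Wnt list median was -0.46, -0.67 and -0.10. The cell cycle median on these slides was -1.32, -1.76 and 0.08; the last of them held vehicle F.

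**Figure D2:**
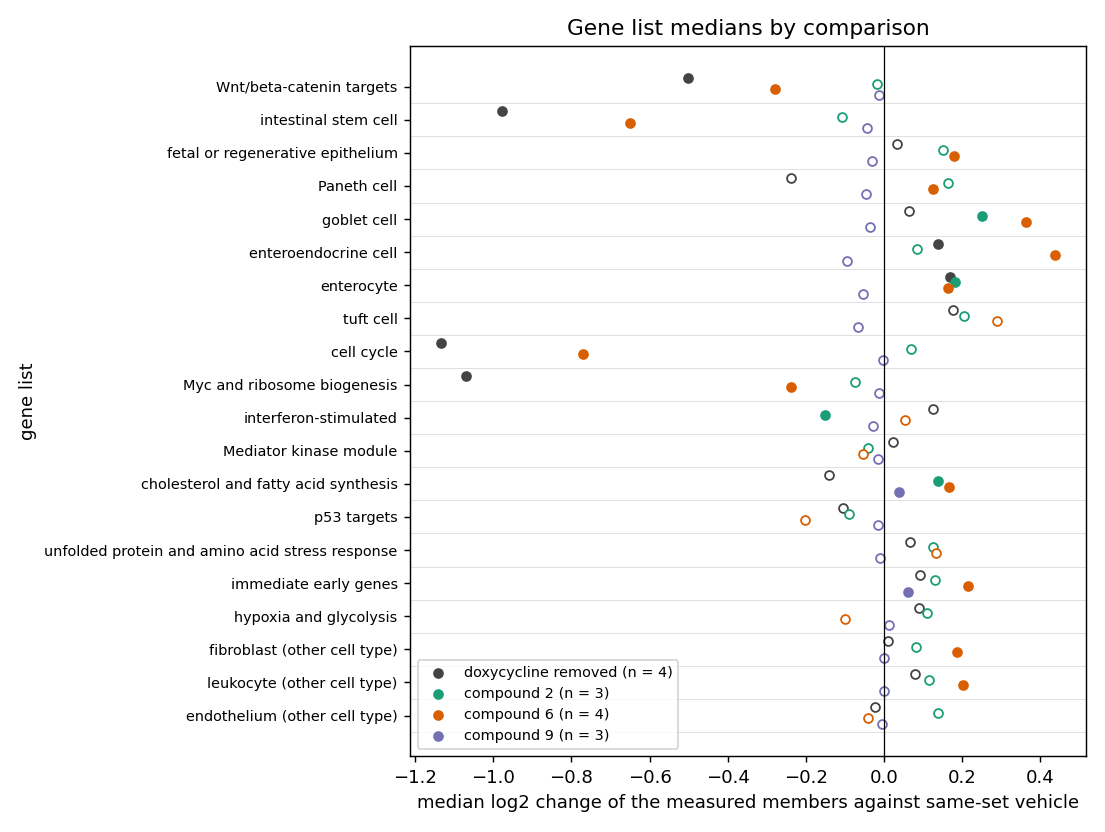
Median log2 change of the measured members (x axis) of 20 gene lists (y axis) against the vehicle arrays with the same letters, after doxycycline withdrawal (n = 4) and with compounds 2 (n = 3), 6 (n = 4) and 9 (n = 3); filled points have a camera adjusted p under 0.05 with the preset correlation. The Wnt list lies at -0.50 after withdrawal, -0.28 with compound 6 and -0.02 with compound 2.

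With compound 9 (3 arrays against 3) none of the Wnt and stem cell genes named above passed. Axin2 lay at -0.15 (95% interval -0.68 to 0.38), Ascl2 at -0.23 (-0.99 to 0.53), Lgr5 at -0.08 (-1.18 to 1.03) and Myc at 0.06 (-0.46 to 0.59). The lower start of Myc and of the stem cell list in vehicles A to C limits these values too. Cdk8 (0.08 ± 0.09) and Cdk19 (0.03 ± 0.10) did not pass either. No member of any of the 20 lists passed. As lists, cholesterol and fatty acid synthesis (median 0.04, adjusted p = 4.56e-05) and immediate early genes (median 0.06, adjusted p = 0.0201) lay higher, with adjusted p = 0.561 and 0.987 with an estimated correlation. Of these list calls 1 was lost with Agilent's log ratios and 1 with the Cy3 channel alone. The other 18 had an adjusted p from 0.662 (tuft cell) to 0.959, and the Wnt list a median of -0.01. With limma 0 of 21487 genes passed (smallest adjusted p = 0.789), 250 had an unadjusted p under 0.05, and the median unadjusted 95% interval reached 0.245 to each side. In simulated data of the compound 2 design, with as many arrays, 47.8% of changes of 0.5 and 97.0% of changes of 1 passed. Those data held many changed genes, which eases the adjustment over genes, so they set no bound for a comparison with 0 passing genes. Gstm1, at 0.72 ± 0.15 (adjusted p = 0.789), and Cyp3a41b, at 1.24, did not pass here, so changes of that size could be missed. With the letter as a block 1 gene passed, the cytochrome Cyp3a41b (1.24, adjusted p = 0.0358). With trend, robust and weight options 3 passed, namely 4930415C11Rik, Cyp2c55 and the glutathione transferase Gstm4 (adjusted p = 0.0396 each), and without every letter F array these 3 and Cyp3a41b. These 4 were named after their values were seen. Their changes rest on letters A to C, so leaving out the letter F arrays altered only the shared estimate of spread. The other Gstm4 probe lay at 0.0664 with compound 9.

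The analogues were then compared with each other at the same dose and time; the labels name no structural difference between them. Compound 9 lay below compound 2 for Cbr3 (-2.83 ± 0.34, adjusted p = 8.8e-05), for the oxysterol-binding gene Osbpl1a (-2.26 ± 0.21; 1 of its other probes lay at 0.24 with compound 2, 0.0297 with compound 9 and -0.31 with compound 6) and for Saa2 (-2.18 ± 0.20), and above it for Tnfrsf19 (1.51 ± 0.23, adjusted p = 8.72e-04) and Sort1 (1.27 ± 0.12). The goblet cell list was lower with compound 9 (1 lower, 17 did not pass of 18, 4 lower adjusted over the list alone; median -0.31, adjusted p = 4.76e-05). It passed with an estimated correlation too (adjusted p = 0.0348), but not with the letter as a block besides (adjusted p = 0.188). Axin2 differed by 0.82 (95% interval 0.29 to 1.35; adjusted p = 0.0684, with the letter as a block 0.00131), and the Wnt list did not pass (4 higher, 24 did not pass of 28; adjusted p = 0.0938). With limma 1026 genes differed, 317 higher and 709 lower with compound 9. The count was 3403 with the letter as a block, 2081 without every letter F array, 224 without the set term, 498 without compound 2 A, 611 without compound 2 C and 616 without compound 9 A. The share higher, 30.9%, was 46.3% with Agilent's log ratios and 45.3% with the Cy3 channel alone.

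Compounds 6 and 2 were scanned on different days, so each was set against the vehicle arrays of its own letters and the difference of these changes was tested. Compound 6 gave the larger rise of the alcohol dehydrogenase Adh6a (difference 2.62 ± 0.27, adjusted p = 2.6e-04), Runx1 (2.02 ± 0.31, adjusted p = 0.0061) and Gclc (1.91 ± 0.26, adjusted p = 0.00172), and the smaller change of Osbpl1a (-2.47 ± 0.28, with the same limit from that probe) and Saa2 (-2.18 ± 0.26). Adh6a lay at -0.76 with the series matrix and -0.26 without the set term. Axin2 differed by -0.11 (95% interval -0.81 to 0.58) and Myc by -0.16 (-0.86 to 0.54), which leaves room for differences of that size. Ascl2 differed by -1.28 (-2.29 to -0.27; adjusted p = 0.214, with the letter as a block 0.0197) and Lgr5 by -2.18 (-3.64 to -0.72; adjusted p = 0.14, with the letter as a block 0.0312). The stem cell list (1 lower, 24 did not pass of 25, 8 lower adjusted over the list alone; median -0.35, adjusted p = 9.78e-06) lay lower with compound 6. So did the cell cycle list (0 of 26; median -0.81, adjusted p = 1.58e-06), whose starting level differed between the vehicle sets. With an estimated correlation the adjusted p of the stem cell and cell cycle lists was 0.355 and 0.715. The stem cell list also started apart, by -0.60 between vehicles A to C and D to G (-0.89 without vehicle F). By array medians it moved least with compound 6 in letter F, from 0.24 in vehicle F to 0.08 in compound 6 F. The low vehicle F is itself the value subtracted there, so a small fall was favoured in advance. The lower start in vehicles A to C limits its difference between the compounds as well. The enteroendocrine list lay higher (0 of 23, 5 adjusted over the list alone; median 0.34, adjusted p = 1.58e-06, adjusted p = 0.291 with an estimated correlation), and its starting level differed more, by -2.54 between vehicles A to C and D to G.

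With limma 121 genes differed between compounds 6 and 2, 74 higher with compound 6, and this count was not stable. It was 1977 with the letter as a block, 9120 without the set term, 2438 with trend, robust and weight options, 1536 without every letter F array, 40 with only the arrays of these groups, 36 with Agilent's log ratios and 37 with the series matrix. Without 1 array it was 1589 (vehicle F), 486 (compound 6 G), 71 (vehicle D), 70 (compound 6 E), 67 (vehicle B), 66 (compound 6 D), 61 (vehicle E), 56 (vehicle G and compound 2 C), 47 (compound 2 B) and 45 (compound 2 A and vehicle A). The share higher, 61.2%, was 74.0% with the Cy3 channel alone and 78.4% with the series matrix, and of the 10 genes with the largest differences 5 lost their call without 1 array; those are not named here.

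Compound 6 also differed from compound 9. Cbr3 was higher by 3.25 ± 0.45 (adjusted p = 4.68e-04), Runx1 by 3.17 ± 0.31 (adjusted p = 3.43e-05), Fgf18 by 2.76 ± 0.32 and Gclc by 2.71 ± 0.26. Rgcc, a cell cycle regulator, was lower by -2.36 ± 0.45 (adjusted p = 0.0058) and Ascl2 by -2.02 ± 0.48 (adjusted p = 0.0196, without vehicle A 0.0509). Axin2 differed by -0.93 (95% interval -1.63 to -0.24; adjusted p = 0.103, with the letter as a block 0.0037). Of 25 stem cell genes 7 were lower and 18 did not pass (15 adjusted over the list alone; adjusted p = 7.72e-07, adjusted p = 0.167 with an estimated correlation). The different starting level of this list in the vehicle sets (-0.60, A to C minus D to G) limits this difference as well. With limma 1390 genes differed, 819 higher with compound 6. The count was 4667 with the letter as a block, where the balance turned (2271 higher and 2396 lower with compound 6). It was 3474 without every letter F array, 898 with Agilent's log ratios, 492 with only the arrays of these groups and 8971 without the set term. Without 1 array it was 3638 (vehicle F), 881 (vehicle D), 861 (compound 9 B), 777 (compound 9 A), 765 (vehicle E), 759 (vehicle A) and 753 (vehicle G).

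The series sets the compounds beside doxycycline withdrawal. Compound 6 lay above withdrawal, on the same letters, in Runx1 (3.23 ± 0.20, adjusted p = 3.27e-08), Cyp2c55 (2.49 ± 0.20) and Fgf18 (2.39 ± 0.21), and below it in the probe of Mup4 (-2.74 ± 0.58, adjusted p = 0.00366). Myc was higher by 1.96 ± 0.22 (adjusted p = 9.63e-06). Of 24 genes of Myc and ribosome biogenesis 17 were higher with compound 6 and 7 did not pass (20 adjusted over the list alone; median 0.79, adjusted p = 1.81e-11, adjusted p = 0.308 with an estimated correlation). Of 28 Wnt targets 9 were higher and 19 did not pass (11 adjusted over the list alone; adjusted p = 5.72e-04, adjusted p = 0.308 with an estimated correlation). Axin2 differed by 0.28 (95% interval -0.18 to 0.73) and Ascl2 by 0.94 (0.28 to 1.60; adjusted p = 0.0516, with the letter as a block 0.00203). With limma 3210 genes differed, 1563 higher with compound 6; the count was 7304 with the letter as a block, 5474 with trend, robust and weight options and 1136 without the set term. The share higher was 48.7%, and 38.1% with the Cy3 channel alone. With the letter as a block the balance turned, with 4161 genes higher and 3143 lower.

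Against withdrawal, compound 2 left the DNA replication gene Mcm6 higher by 3.65 ± 0.55 (adjusted p = 0.00168), the transporter Slc12a2 by 3.05 ± 0.54, Ascl2 by 2.22 ± 0.48 (adjusted p = 0.0156) and Myc by 2.12 ± 0.33 (adjusted p = 0.00197). Of 28 Wnt targets 7 were higher and 21 did not pass (11 higher and 1 lower adjusted over the list alone; adjusted p = 4.14e-05, adjusted p = 0.371 with an estimated correlation). Compound 9 left Ascl2 higher by 2.96 ± 0.48 (adjusted p = 0.00733), Pla2g5 by 3.43 ± 0.55 and Myc by 2.15 ± 0.33 (adjusted p = 0.00539). Of 28 Wnt targets 9 were higher and 19 did not pass (14 higher and 1 lower adjusted over the list alone; adjusted p = 7.19e-08, adjusted p = 0.175 with an estimated correlation). With limma 907 genes differed for compound 2, 635 higher, and 330 for compound 9, 241 higher; with the letter as a block 4895 and 4999. The shares higher were 70.0% and 73.0%. That of compound 2 was 49.7% with Agilent's log ratios, 42.5% with the Cy3 channel alone and 54.0% with the series matrix; that of compound 9 was 52.2% with the Cy3 channel alone.

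Each of these is a difference between changes in sets whose vehicles started apart, which limits what can be read from it. Vehicles A to C and D to G had means of -2.80 and -1.18 for Myc, 3.30 and 4.15 for Ascl2, 0.62 and 1.72 for Pla2g5, and -2.94 and -2.37 for Mcm6. The counts moved with single arrays and with the processing. For compound 2 against withdrawal the count was 3338 without vehicle F, 556 without withdrawn G, 551 without withdrawn F, 537 without withdrawn D, 475 without vehicle C, 458 without vehicle G, 437 without compound 2 A, 407 without vehicle E, 402 without vehicle D, 373 without vehicle A and 366 without compound 2 C. For compound 9 it was 3772 without vehicle F, 202 without vehicle B, 167 without withdrawn E, 100.0 without compound 9 C, 93 without withdrawn F, 89 without withdrawn D, 59 without withdrawn G, 53 without compound 9 B, 47 without vehicle A, 46 without vehicle C or vehicle G, 45 without compound 9 A, 40 without vehicle E and 33 without vehicle D. With only the arrays of these groups 449 and 32 genes differed.

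The genes that moved on withdrawal were set against those that moved with each compound. Compound 6 moved 2087 of the 4449 the same way, 814 up and 1273 down, where independence would give 178 and 387, and 85 the opposite way. Across genes, which are not independent replicates, the changes correlated at 0.613, and the shared vehicle arrays alone gave 0.499 in 100 simulated draws; their covariance was 0.0669, and 0.00948 in the draws. With the 4 vehicle arrays split into pairs, 1 pair for each side, the 6 splits gave 332 to 912 genes the same way, at most 170 opposite and correlations of 0.231 to 0.607. The correlation was 0.577 to 0.607 with vehicle F on the withdrawal side and 0.231 to 0.370 with it on the compound 6 side. Each split leaves treated letters without the vehicle of their own letter, so letter differences enter these values. Compound 2, which shares no vehicle array with withdrawal, moved 316 the same way (181 up and 135 down, where independence would give 51.5 and 56.9) and 52 opposite, with a correlation of 0.261. Compound 9 had 0 passing genes, so its number was 0 in advance. Its changes correlated with those of withdrawal at -0.0602. Compounds 2 and 9 share 3 vehicle arrays, and their changes correlated at 0.283 where these arrays alone gave 0.50. Compounds 2 and 6, also without shared arrays, moved 790 genes the same way and 5 opposite, with a correlation of 0.568. With the letter as a block the numbers moved the same way as withdrawal were 4669, 1511 and 1 for compounds 6, 2 and 9, with 381, 334 and 0 moved the opposite way, and without every letter F array 3854, 938 and 3. For compound 6 it was 1218 without the set term.

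**Figure D3:**
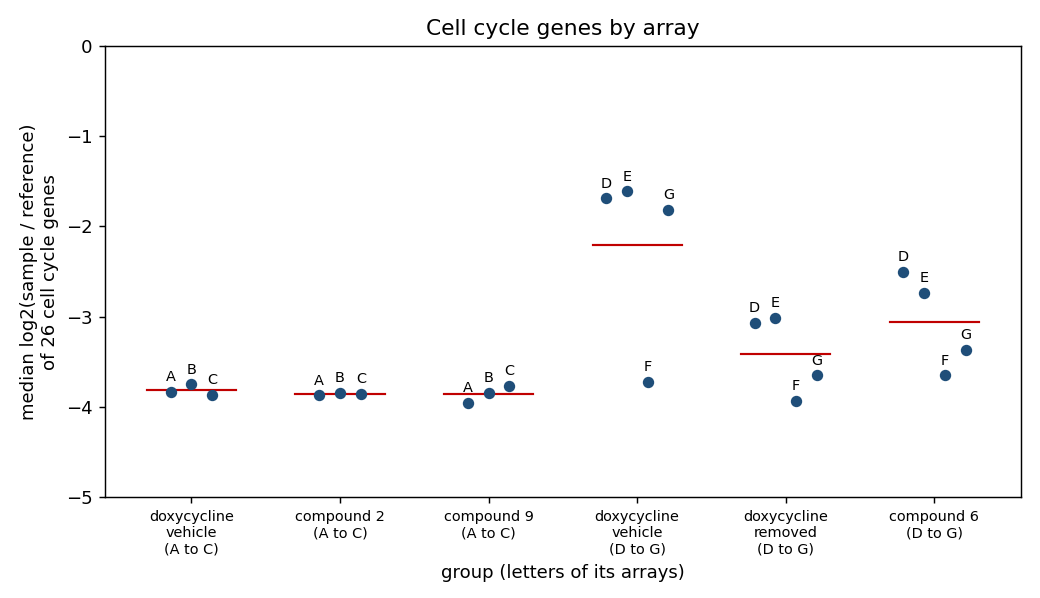
Median log2 sample over reference (y axis) of 26 cell cycle genes on each array, by group (x axis), with the letter of each array beside its point and the group mean as a line. Vehicles D, E and G lie between -1.82 and -1.61, vehicle F lies at -3.72 and vehicles A to C have a mean of -3.82.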

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

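Chosen only after the result was seen were the tests of vehicle F as a mislabelled array with its bound, of its slide, of a culture state shared by letter F, of the low starting level of cell cycle genes, of a difference between the compounds and of noisier compound 9 arrays; the tests of probe signal, of a weak compound 9 response and of other splits were set before.

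In the 3 groups of letters D to G, 20 list medians and 17 panel genes were searched for an array far from the other 3. Of the 111 groups of values searched, 16 held one, where chance gives about 1 in 20; 13 of the 16 lay in letter F arrays and 7 in vehicle F. In vehicle F the cell cycle list lay at -3.72 (others -1.82 to -1.61), the Myc and ribosome list at -1.94 (-0.88 to -0.72), the p53 list at -0.47 (-0.03 to 0.05) and the tuft cell list at 1.16 (0.45 to 0.48). Lgr5 lay there at 1.00 (3.71 to 4.24), Ascl2 at 3.29 (4.37 to 4.49) and Mki67 at -4.93 (-2.06 to -1.82).

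In compound 6 F the Paneth cell list lay at 2.47 (4.17 to 4.26), the Myc and ribosome list at -1.75 (-1.31 to -1.23), Muc2 at 5.50 (5.32 to 5.33) and Ctnnb1 at 0.78 (0.70 to 0.72). In withdrawn F the tuft cell list lay at 1.43 (0.78 to 0.79) and the fetal epithelium list at -2.59 (-3.47 to -3.32). Outside letter F, the stem cell list lay at 0.0594 in withdrawn E (-0.12 to -0.10), the enteroendocrine list at 3.67 in compound 6 G (3.42 to 3.43) and the fibroblast list at -4.74 in vehicle D (-5.11 to -5.07).

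The low cell cycle level of vehicle F was weighed against a wrong label, its slide and a state shared by the letter. Were vehicle F a withdrawn array, it should resemble withdrawn F, yet over 30 Wnt and stem cell genes that fall without the letter F arrays withdrawn F lay below it by a median of -0.58. That is beyond the largest median difference between withdrawn arrays, 0.112, with 27 of 30 genes lower, which argues against the wrong label; the drop was smaller than in letters D, E and G (-1.46, -1.44 and -1.51). Vehicle D, on the same slide, lay at -1.69, near vehicles E and G, which argues against the slide. Letter F was the lowest of the 4 letters in 3 of 3 groups (withdrawn F at -3.93), so a culture state shared by the letter F samples is a candidate explanation, found on the same data; no biological explanation was tested beyond it.

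Cell cycle genes were lower with compound 6 and not with compound 2, and the difference between the changes passed as a list (median -0.81, camera adjusted p = 1.58e-06, 0.715 with an estimated correlation). Probes at background are argued against: 92.3% of the list (24 of 26 genes) stood well above background on every one of vehicles A to C. That flag does not show how far a low signal above background could still fall. A low starting level may account for it, though the test of this cannot decide. In letter F, whose vehicle was low too, the list moved by 0.11 with compound 6, against -0.85, -0.98 and -1.36 in letters D, E and G. Letter F was singled out for its low vehicle, which is also the value subtracted. A small fall there was thus favoured in advance. Vehicles A to C, the controls of compound 2, lay at -3.82 ± 0.06 against -1.71 in vehicles D, E and G. A difference between the compounds cannot be told apart from an effect of the starting level, because no array holds compound 2 at the higher level.

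With limma 0 genes passed with compound 9, 250 had an unadjusted p under 0.05, and 1, 3 and 4 passed with the letter as a block, with trend, robust and weight options, and without every letter F array. Noisier arrays are argued against, since the median SD between its arrays was 1.07 times that of compound 2. A weak response in the direction of compound 6 across its genes as a whole is argued against too. Over the 5323 genes that moved with compound 6 the slope of compound 9 changes on compound 6 changes was 0.00790, with 49.95% of signs shared. That of compound 2 was 0.407. Leaving out 1 compound 9 array in turn gave slopes of 0.00178 to 0.0132, while vehicle arrays were not left out for this range. A response in a part of them stays open, as do a lower exposure or potency, which were not tested. Cyp3a41b, Gstm4, Cyp2c55 and 4930415C11Rik, which passed in alternatives, lay at 1.24, 0.58, 1.15 and 0.76 with compound 9. With compound 6 they lay at 2.20, 1.99, 0.98 and 2.27. The other Gstm4 probe lay at 0.0664 with compound 9 and 0.906 with compound 6. A list of NRF2 targets, chosen after the data were seen, lay higher with compound 9 (median 0.08, camera p = 0.0348 with an estimated correlation).

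Other splits of the same arrays were counted for each comparison. With the letters left aside, the count for compound 6 against vehicle (5323 genes, highest other 4470) was reached by 1 of 35 splits. So was that for compound 6 against withdrawal (3210, highest other 119). The letters pair the arrays, though, so the 35 splits cannot be exchanged freely. The 8 splits that part all 4 letters are too few for a share under 0.05, and chance is not called excluded. Compound 6 against compound 9 (1390 genes, highest other 389) and compounds 2 and 9 against withdrawal (907 and 330, highest other 0) were each reached by 1 of 35 splits. Among these the real split alone follows the letter sets, so the arrays cannot be exchanged and chance is not called excluded; without vehicle D the 330 became 33, and without vehicle F 3772. For withdrawal against vehicle (4449) 3 of 35 splits gave as many, up to 5735 with withdrawn D, F and G and vehicle F set against the rest, so chance is not excluded by this count. That split exchanges vehicle F with withdrawn E and leaves 6 of the 8 arrays in their groups. The other splits with the highest counts (2551 and 4859, and 3857, 3983 and 4470 for compound 6) also exchange vehicle F with 1 treated array, which points to a structure of the samples around vehicle F; with the letter as a block 8389 and 8853 genes passed. Among the 7 other splits that part all 4 letters the highest gave 4 genes for withdrawal, 10 for compound 6 against vehicle and 0 for compound 6 against withdrawal. For compound 6 against compound 2 (121 genes) 2 of 35 splits gave as many, up to 245 with compound 6 G beside the compound 2 arrays. These arrays too lie in different letter sets and cannot be exchanged, so this count decides nothing and chance is not excluded. For compound 2 against vehicle (1130, highest other 1), compound 9 against vehicle (0 genes, reached by 10 of 10, highest other 83) and compound 9 against compound 2 (1026, highest other 2) the 10 splits are too few for a share under 0.05.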

How the results depend on the processing

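Leaving out every letter F array, and the slide block for the lists, were tests chosen after the data were seen; the other alternatives were not. Scaling of average intensities between arrays after loess changed no count and the scan day block is identical to the set term, so neither tests stability. With 42.6% to 51.9% of spots well above background, changes of dim genes are the least certain. The count for compound 6 stayed within 1.5 times its value under all alternatives but the letter block and the arrays of the compared groups alone, and that for compound 6 against withdrawal under all but the letter block, the model without the set term and the trend, robust and weight options. The causes of the changes below were not tested, except that the arrays of the compared groups alone leave fewer arrays for the estimate of spread.

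The letter as a block gave 8389 for withdrawal, 3707 for compound 2, 8853 for compound 6, 1 for compound 9, 3403 for compound 9 against 2, 1977 for compound 6 against 2, 4667 for compound 6 against 9, and 7304, 4895 and 4999 for compounds 6, 2 and 9 against withdrawal. The numbers moved the same way as withdrawal were 1511, 4669 and 1 for compounds 2, 6 and 9. The block ended the call of 0 named genes and added 33 calls. With trend, robust and weight options the counts were 8779 for withdrawal, 3309 for compound 2, 3 for compound 9, 3036 for compound 9 against 2, 2438 for compound 6 against 2, 4292 for compound 6 against 9, and 5474, 4910 and 4618 for compounds 6, 2 and 9 against withdrawal.

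Without every letter F array they were 6850, 2299 and 4 for withdrawal and compounds 2 and 9, 2081 for compound 9 against 2, 1536 and 3474 for compound 6 against 2 and 9, and 3434 and 3808 for compounds 2 and 9 against withdrawal; moved the same way were 938, 3854 and 3. With only the arrays of the compared groups they were 2086, 651 and 3091 for withdrawal and compounds 2 and 6, 40 and 492 for compound 6 against 2 and 9, and 449 and 32 for compounds 2 and 9 against withdrawal. With Agilent's log ratios they were 36 and 898 for compound 6 against 2 and 9, and 584 and 115 for compounds 2 and 9 against withdrawal; with the series matrix 37 for compound 6 against 2, and 604 and 98 for compounds 2 and 9 against withdrawal. Without the filter compound 9 against withdrawal gave 200 genes.

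Without the set term they were 2126 and 3636 for withdrawal and compound 2, 224 for compound 9 against 2, 9120 and 8971 for compound 6 against 2 and 9, and 1136, 7279 and 6096 for compounds 6, 2 and 9 against withdrawal, with 1218 moved the same way for compound 6. Of the 20 lists, those that then passed and had not before, with their direction kept, were 5 with compound 2 (Wnt at adjusted p = 0.0218, stem cell, fetal, Myc and ribosome, and immediate early genes), 4 after withdrawal (tuft cell, lipid synthesis, p53, and hypoxia and glycolysis), 2 with compound 9 (enteroendocrine and tuft cell) and 1 with compound 6 (tuft cell). No longer passing, with their direction kept, were 6 lists with compound 6 (Wnt at 0.185, fetal, Paneth, cell cycle, lipid synthesis and immediate early genes) and the enterocyte list with compound 2. Lists that turned their direction there, among those passing before or then, were, with compound 2, enteroendocrine (adjusted p = 0.00558) and cell cycle (0.00744), which had not passed before, and interferon-stimulated genes (0.345), which had. They were Myc and ribosome genes with compound 6 (0.38), which had passed before, and with compound 9, where none of the 4 had, stem cell (0.0211), cell cycle (7.57e-06), Myc and ribosome (4.55e-05) and interferon-stimulated genes (3.75e-04). With an estimated correlation 0 of 25 list calls held in the comparisons with vehicle, the Wnt list lying at 0.204 for withdrawal and 0.442 for compound 6. Agilent's log ratios lost 1 list call after withdrawal, 2 with compound 6 and 1 with compound 9, and added 1 each with compounds 2 and 6. The Cy3 channel alone lost 1 each with compounds 2, 6 and 9, and added 1 after withdrawal and 2 with compound 6. The slide block lost 1 after withdrawal and added 1 with compound 6.

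Named genes turned their sign without the set term as follows. Sp5 lay at 0.34 after withdrawal, 0.26 with compound 6, 3.45 and 2.87 for compound 6 against 2 and 9 and -3.52 for compound 2 against withdrawal. With compound 2 the complement gene C2 lay at 0.27 and Vil1 at -0.0023, and with compound 6 Polr1a at 0.0194. For compound 6 against 2 Adh6a lay at -0.26, Alpi at 0.44, Chga at 4.23 and Myc at 1.46, and Myc at 1.44 against 9. For compound 2 against withdrawal Chga lay at -4.22 and Lgr5 at -0.22, and for compound 9 Bcl2l15 at 0.37, Fas at 0.50, Gdpd2 at 0.46 and Kcnk5 at 0.26. With Agilent's log ratios Apoc3 lay at -0.0185 with compound 2, Clca1 at -0.17, Muc2 at -0.0218 and Neurod1 at -0.0855 with compound 6, and Spaca3 at 0.0362 for compound 6 against 2. With the Cy3 channel alone Apoc3 lay at -0.53 and Vil1 at -0.21 with compound 2. With the series matrix Kcne3 lay at 1.97 after withdrawal, Clca1 at -0.0637 and Adh6a at -0.73 with compound 6, and Adh6a at -0.76 for compound 6 against 2.

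Leaving out 1 array in turn gave 2422 to 7411 genes for withdrawal, 546 to 887 for compound 2, 3747 to 7349 for compound 6, 0 to 0 for compound 9, 498 to 1078 for compound 9 against 2, 45 to 1589 and 753 to 3638 for compound 6 against 2 and 9, and 2278 to 4248, 366 to 3338 and 33 to 3772 for compounds 6, 2 and 9 against withdrawal. Vehicle F gave the highest counts for withdrawal (7411), for compound 6 against 2 and 9 (1589 and 3638) and for compounds 2 and 9 against withdrawal (3338 and 3772). The adjusted p of the Wnt list ranged from 3.89e-08 to 5.54e-07 for withdrawal, 0.0831 to 0.28 for compound 2, 4.94e-04 to 0.0318 for compound 6 and 0.499 to 0.988 for compound 9. Of the named genes that passed, 6 of 44 after withdrawal, 11 of 31 with compound 2 and 8 of 73 with compound 6 lost their call without 1 array, and 27, 20 and 39 under at least 1 of the alternatives.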

Other observations

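The list of 30 targets of the transcription factor NRF2, which drives glutathione synthesis and detoxification, both tests on it and the comparison of the vehicle sets were chosen after the data were seen. With compound 6, 25 of its 30 genes rose, 0 fell and 5 did not pass (median 0.80, camera p = 1.25e-24, p = 3.34e-04 with an estimated correlation). With compound 2, 14 rose, 0 fell and 16 did not pass (median 0.33, p = 8.46e-15, p = 0.00324 with an estimated correlation). The quinone reductase Nqo1 rose by 1.03 ± 0.15 with compound 6 and 0.69 ± 0.17 with compound 2, glutathione reductase, Gsr, by 1.31 ± 0.10 and 0.43 ± 0.11, and the cysteine ligase subunit Gclm by 1.16 ± 0.12 and 0.52 ± 0.14. The haem oxygenase Hmox1 did not pass, at 0.06 ± 0.14 and 0.10 ± 0.16. After withdrawal 11 rose and 2 fell (median 0.19, p = 1.03e-05, p = 0.0655 with an estimated correlation). With compound 9 none passed, and the list lay higher as a whole (median 0.08, p = 2.59e-07, p = 0.0348 with an estimated correlation). The list was lower with compound 9 than with compound 2 (10 of 30 genes lower, median -0.26, p = 4.32e-10, p = 0.0131 with an estimated correlation) and higher with compound 6 than with compound 2 (3 of 30 higher, median 0.33, p = 7.04e-13, p = 0.00555 with an estimated correlation).

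A hypothesis is that compounds 2 and 6 may raise NRF2 targets as a group, beyond the genes that drew attention. The 25 members other than Gclc, Gstm1, Osgin1, Cbr3 and Akr1b8, which the rule for named genes had picked, had a median of at least 0.268 with both compounds. Their test passed in both. Because the whole list was chosen after the data were seen, these 25 are not independent of the data. Their p-values are not adjusted over lists, and the letter was not fitted as a block. The pass therefore leaves the hypothesis untested. Whether this is separate from Wnt output stays open: the same 25 genes had a median of 0.145 after withdrawal (camera p = 0.00268, p = 0.114 with an estimated correlation), neither at or below 0 nor passing both ways.

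The vehicle arrays of the sets differed from each other: 9673 genes differed between vehicles D to G and A to C, 5183 of them higher in D to G, and 11905 without vehicle F. As means of list medians, A to C minus D to G, enteroendocrine genes differed by -2.54 (-2.79 without vehicle F), cell cycle genes by -1.60 (-2.11), Myc and ribosome genes by -1.31 (-1.60), stem cell genes by -0.60 (-0.89), Paneth cell genes by 0.89 (0.42) and interferon-stimulated genes by 1.12 (1.11). The sets were scanned on different days with different scanners, so the cultures and the scans cannot be told apart here.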
